A study of Mus musculus with 2 samples.

How the data were processed

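DNase-seq measures where the nuclease DNase I cuts the DNA of isolated nuclei, so that accessible regulatory DNA appears as stretches rich in cuts. The samples were cerebellum tissue from 2 male mice of the strain B6CASTF1/J, an F1 hybrid of C57BL/6J and CAST mice, aged 36 days, 1 library per animal. Both animals form 1 group. The labels number them as biological replicates 1 and 2 but give both the same donor entry, so the spread between them may hold little more than the difference between similar animals and library preparations. With 1 group there was no comparison between groups, and no test across animals was possible.

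Per the labels and the deposited file descriptions, all coordinates are on the mouse assembly mm10 and each animal's files derive from that animal's own alignments, so peaks were called per animal with no pooling. The aligner and the peak and footprint callers are not given in the sources used here. For each animal the authors deposited a larger and a smaller peak list, a list of footprints, and a file of false discovery rates along the genome. The peak value is a signal, the height the authors deposited for each peak. It was used to describe, rank and filter peaks within an animal's own list, in a correlation of shared peaks, to match unshared peaks of both animals for GC content, and as a count of steps to match peaks for footprints. Heights in the larger list lay on a grid of equal steps, with all values within 0.1 of a step of a whole number of steps in both animals. The steps were 0.00542 and 0.00988 in replicates 1 and 2. If a step is 1 cut under a scaling per library, which the sources used here do not state, replicate 1 was the deeper library. The depth is otherwise unknown, and no interval was computed from it.

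The false discovery rates are a p-value type of measure, and the authors' deposited file lists only stretches below 0.05. Every peak of the larger list touched a base at or below 0.05, and every peak of the smaller list a base at or below 0.001. The larger list was the main one. Stretches at or below 0.05 were merged into regions. Every footprint carries the same deposited p-value type of entry, 0.01, which was read as the threshold of the call, so footprints were used only through their positions.

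The reference was GRCm38.p6 with the GENCODE M21 annotation, whose 21829 protein-coding genes (1 entry per symbol) and 33475 other genes were used. No peak extended past a chromosome end. A promoter window covered 1000 bp on both sides of every annotated start of a protein-coding transcript. A gene was called accessible at its promoter when any peak overlapped a window. Each peak was assigned by its midpoint to promoter, exon, intron or intergenic sequence, in that order.

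The choices of gene lists, motifs, windows, tests and most alternatives were made before the data were examined. The 23 gene lists were 17 curated lists and 6 families defined by symbol. The curated lists covered granule cells, Purkinje cells, interneurons and unipolar brush cells, astrocytes and Bergmann glia, the oligodendrocyte lineage, microglia and macrophages, endothelial and mural cells, choroid plexus, forebrain neurons, synapse and other neuronal genes, immediate early genes, housekeeping genes, liver, striated muscle, blood and lymphoid cells, germline, and keratinocytes and epithelia. The families were Hox genes, olfactory receptors, vomeronasal receptors, clustered protocadherins, histones and cytosolic ribosomal proteins. All listed genes were annotated. Among the curated lists, Cspg4 and Snap25 each stand in a pair. The housekeeping list also holds the ribosomal protein genes Rpl13a and Rps18.

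Promoter accessibility of each list was compared with all other protein-coding genes by a two-sided Fisher's exact test in each animal, with Benjamini-Hochberg adjustment over the 23 lists. For distal accessibility, peaks outside promoter windows were counted in the gene body and 10000 bp on both sides. The median per list was ranked among 10000 random lists of the same size, matched on territory length in 20 classes, as a two-sided permutation test adjusted over the 23 lists. Footprint occupancy was the share of consensus occurrences inside peaks whose centre base lay in a footprint. It was compared with the same consensus read backwards, which keeps base composition but can change CpG content, by a two-sided Fisher's exact test. Of 28 motifs, 27 were tested. The SP/KLF consensus reads the same backwards and was set only beside the share of peak bases in footprints. A call needed an adjusted p below 0.05 in both animals with the same direction. The direction of a motif was taken from the difference of the shares, a choice made after NRF1, which has no ratio in replicate 2, was seen. Genes, peaks and motif sites are not independent replicates, so these p-values describe each animal's own map.

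Peaks were shared when they overlapped a peak of the other animal by at least 1 bp, and the chance level came from 100 random placements on the same chromosome outside assembly gaps. Footprints were shared at an overlap of at least 50% of the shorter, beside 20 random placements within the same regions.

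Named genes followed a rule. Per list, the 3 genes with the highest mean percentile rank of their strongest promoter peak were taken, with the first 2 genes in alphabetical order that lacked a promoter peak in both animals. From each list called for distal peaks the 2 genes with the most such peaks were added. Per animal, 5 genes were taken whose promoter peak ranked highest while the other animal had no region in the window. All called motifs, the 5 strongest shared peaks and the 5 widest regions per animal were also taken. Some genes the rule took are not reported here. Names outside the rule are said to be so where they appear.

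Alternatives changed the promoter window (500 bp upstream to 100 bp downstream, or 2500 bp on both sides), the territory (gene body only, or 50000 bp on both sides) and the list summary (mean for median). Others used regions for peaks, peaks above the list's median height, the same number of peaks in both animals, the strongest 10000 peaks, autosomes only, or another overlap rule. Further ones matched genes on promoter CpG observed to expected ratio in 5 classes (a two-sided exact test stratified by class), changed the occupancy rule, split peaks by promoter, used false discovery rates of 0.01 and 0.001, or left out each animal. The smaller peak list was chosen after seeing the data as an alternative for annotation, promoters and distal peaks.

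The interval counts, the promoter and distal list tests, the motif scan and the motif test were run on simulated data with known answers, and the other steps were not. Simulated promoter lists of 20 genes and simulated distal lists, both over 21829 genes, were all recovered with 0 false calls among unchanged lists. The motif scan recovered all planted sites of the 28 consensus sequences. Over 500 simulations, the motif test recovered all changed cases and called 4.2% of unchanged ones before adjustment. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.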

Results

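Chromatin accessibility was mapped by DNase-seq in cerebellum from 2 male B6CASTF1/J mice aged 36 days, which form 1 group. Replicate 1 had 140127 peaks and replicate 2 had 114404, a mean of 127266 ± 18189 (SD, n = 2). Peaks covered 25.2 and 22.1 Mb, or 0.950% and 0.836% of the ungapped genome, with median widths of 180.0 and 187 bp. Accessible regions at a false discovery rate of at most 0.05 numbered 207419 and 179591 and covered 43.8 and 39.2 Mb. Footprints, short stretches protected from cutting inside accessible DNA, numbered 342409 and 262603 with a median width of 11 bp in both animals. A footprint was found in 78.4% of replicate 1 peaks and 72.5% of replicate 2 peaks. Values given in pairs are those of replicates 1 and 2, in that order. Peak heights are the authors' own and describe ranks within an animal's list. Each animal gave 1 library, so the spread between animals includes that between library preparations. Libraries came from cerebellum tissue with its cell types mixed. A promoter without a peak may therefore still be accessible in a cell type that makes up a small part of the tissue.

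Promoters of protein-coding genes held a larger share of peaks than of the genome. Promoter windows held 23.1% ± 1.5 (SD, n = 2) of peak midpoints and 2.44% of ungapped bases, a ratio of 9.50. Exons held 8.29% ± 1.2, introns 39.9% ± 0.37 and intergenic sequence 28.7% ± 0.63 (SD, n = 2 each), beside 4.18%, 40.01% and 53.4% of the genome. Among the strongest 10000 peaks of each animal, promoters held 71.1% ± 0.70 (SD, n = 2). Median heights of promoter peaks were 1.95 and 1.81, against 0.531 and 0.672 for intergenic peaks. With the narrow promoter window the promoter share was 13.2% and the ratio 16.0, and with the wide window they were 29.7% and 5.35. The 5 strongest shared peaks all lay in promoter windows: those of Dynlt1b, a dynein light chain gene (mm10 chromosome 17, 6430021 to 6430180), Hjurp, Bahcc1, Acin1 with 1700123O20Rik, and Nup107, a nuclear pore gene. Their heights ranged from 53.0 to 76.7 in replicate 1 and from 29.7 to 50.5 in replicate 2. The widest regions of replicate 1 lay at Pcdh7, Irs1, Wnt7a, Mex3b and Coro2a, and those of replicate 2 at Sin3a, Marcks, Mex3b, Brd2 with H2-DMa, and Lhx1. The widest of all spanned 6131 bp at Sin3a (chromosome 9, 57071503 to 57077633).

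Granule cell and synapse gene promoters were accessible without exception. All 20 granule cell genes had a promoter peak in both animals, against 67.0% and 63.5% of other genes (Fisher's exact test, adjusted p = 9.1e-04 and 3.9e-04). The strongest were Tiam1, an activator of the small GTPase Rac (heights 27.9 and 17.4), Cbln3, a cerebellin expressed in granule cells (27.9 and 17.1), and Neurod1, a basic helix-loop-helix transcription factor (20.6 and 12.6). The Cbln3 peak also lay in the promoter window of Khnyn. The median granule cell promoter peak stood above 93.4% and 92.9% of the peaks of its own list, which holds peaks of all kinds. It was not tested against accessible promoters alone. The granule cell medians were 9.73 and 7.36. Those of accessible autosomal promoters rose from 0.607 and 0.879 in the lowest of 5 CpG classes to 13.3 and 8.99 in the highest. They were 8.41 and 6.06 in class 3 and 11.1 and 7.66 in class 4. All 20 synapse and neuronal genes were likewise accessible (adjusted p = 9.1e-04 and 3.9e-04 by Fisher's exact test). Among the strongest were Vamp2, a vesicle fusion protein gene (19.4 and 10.7), and Rab3a (14.6 and 12.8). Matched on promoter CpG class, the synapse list kept its call, whereas all granule cell genes stood accessible against 84.5% expected and that call ended (exact stratified test, adjusted p = 0.0859 and 0.0333).

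Other neuron types of the cerebellum were less uniform. Promoter peaks were present at 17 of 20 Purkinje cell genes in both animals, which did not pass the test (Fisher's exact test, adjusted p = 0.134 and 0.0698). Itpr1, the inositol trisphosphate receptor of Purkinje cells (heights 16.0 and 12.5), Lhx1 (13.0 and 9.86) and Plcb4 (12.8 and 7.66) ranked highest. Pcp2, a Purkinje cell marker, and Ppp1r17 had no promoter peak in either animal, nor did Skor2, which was chosen after its values were seen. Of 15 interneuron and unipolar brush cell genes, 13 and 9 were accessible, which did not pass (adjusted p = 0.192 and 0.792, Fisher's exact test). Calb2, the calretinin gene, led this list (12.4 and 7.01), and Ptprk had heights of 3.45 and 2.41. The glycine transporter gene Slc6a5 and Tfap2b had no promoter peak.

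In this mixed tissue, promoters of astrocyte genes mostly had a peak and those of microglial genes mostly had none. Astrocyte and Bergmann glia genes were accessible at 17 and 16 of 17 promoters, with Gfap, chosen after its values were seen, accessible in replicate 1 alone (Fisher's exact test, adjusted p = 0.00231 and 0.0133). Nfia, a transcription factor of the nuclear factor I family, had heights of 22.3 and 14.3, Glul, the glutamine synthetase gene, 13.8 and 8.23, and Nfib 11.9 and 7.83. The Glul peak also lay in the window of Teddm2. This call ended with peaks above the median height, where the share was 50% against 57.6% of other genes, and with the smaller peak list (70.6% against 61.3%). Microglia and macrophage genes were accessible less often than other genes, at 5 and 3 of 16 (Fisher's exact test, adjusted p = 0.00766 and 5.8e-04). Irf8, a transcription factor gene of myeloid cells (heights 2.43 and 1.42), and the complement gene C1qc (2.12 and 1.54) had peaks, while Aif1 and C1qa had none. Matched on CpG class, microglial genes stood at 25% against 37.0% expected and the call ended (adjusted p = 0.707 and 0.174, exact stratified test). Oligodendrocyte lineage genes did not pass, with 11 and 9 of 18 accessible (adjusted p = 0.679 and 0.243, Fisher's exact test). Mbp, which encodes a myelin protein, had heights of 5.39 and 2.77, Myrf 3.45 and 1.76 and Olig1 2.60 and 1.43, while Cspg4 and Ermn had no promoter peak. Endothelial and mural genes were accessible at 9 and 7 of 18 (adjusted p = 0.165 and 0.0564) and choroid plexus genes at 7 and 3 of 10 (adjusted p = 1.00 and 0.0556, Fisher's exact test). Erg, Flt1 and Kcnj8 had heights of at most 1.29, and of the choroid plexus genes Otx2 reached 1.65 and 1.88, Prlr 0.612 and 0.375, and Aqp1 0.537 and 0.365. Ly6c1, Folr1 and Kcne2 had no promoter peak, although Folr1 had an accessible region in its window in both animals. Among peaks above the median height both lists were called lower, at 8.33% and 10% of genes against 57.6% of other genes.

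Forebrain neuron genes were accessible at 13 and 8 of 20 promoters, which did not pass in both animals (Fisher's exact test, adjusted p = 0.853 and 0.0486). Ppp1r1b, a striatal phosphatase regulator (heights 4.14 and 4.02), and the dopamine receptor gene Drd1 (4.36 and 2.39) had peaks, whereas the homeobox genes Dlx1 and Dlx2 had none. Matched on promoter CpG class, this list was called lower, at 52.5% against 91.8% expected (adjusted p = 1.7e-04 and 2.0e-08, exact stratified test). Clustered protocadherins, cell adhesion genes with many alternative promoters, did not pass at 32 and 30 of 56 (adjusted p = 0.152 and 0.140, Fisher's exact test). Pcdhgc3 was the strongest (10.8 and 10), followed by Pcdhac1 (6.54 and 4.04) and Pcdhgc4 (2.05 and 3.08), and Pcdha1 and Pcdha11 had no peak. With CpG matching this list was called lower too, at 55.4% against 78.9% expected (adjusted p = 2.9e-06 and 1.4e-05, exact stratified test), as it was with the narrow window, the smaller list and peaks above the median height.

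Immediate early, housekeeping, ribosomal protein and histone genes had accessible promoters. All 15 immediate early genes, which respond quickly to neuronal activity, had a promoter peak in both animals (Fisher's exact test, adjusted p = 0.00628 and 0.00282). Jun (heights 32.3 and 20.3), Dusp1 (28.9 and 17.8) and Egr1 (27.0 and 16.1) were the strongest. All 20 housekeeping genes were accessible (adjusted p = 9.1e-04 and 3.9e-04, Fisher's exact test), led by Rplp0 (35.6 and 22.7), Ppia (28.9 and 17.3) and Psmb2 (26.4 and 17.6). Cytosolic ribosomal protein genes were accessible at 74 and 73 of 76 promoters (adjusted p = 4.2e-10 and 1.7e-10, Fisher's exact test). Rpl7a (39.8 and 22.1), Rpl23 (33.4 and 17.7) and Rpl15 (25.3 and 18.7) were strongest, and Rpl10l and Rpl3l had no peak. Histone genes were accessible at 60 and 61 of 70 (adjusted p = 9.1e-04 and 4.5e-05, Fisher's exact test). Hist1h3a and Hist1h4a shared a single peak (24.7 and 17), H1f0 had 22.4 and 13.3, and Hist1h1d and Hist1h1t had none. The strongest peak also lay in another gene's window for 28 of 60 histone genes and 14 of 73 ribosomal protein genes accessible in both animals, Rpl7a with Med22 and Rpl15 with Nkiras1 among them. All 4 calls ended with CpG matching, where immediate early genes were expected at 94.6%, housekeeping genes at 94.3% and ribosomal protein genes at 94.1%. Histone genes then stood below the expected share, at 86.4% against 94.3% (adjusted p = 8.4e-04 and 0.0908, exact stratified test).

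Genes of other tissues mostly lacked a promoter peak. Liver genes were accessible at 2 of 20 promoters in both animals (Fisher's exact test, adjusted p = 8.8e-07 and 4.0e-06). The peaks were at Foxa3 (13.5 and 10.8), in a window shared with Sympk, and Apob (2.22 and 1.22), while Ahsg and the albumin gene Alb had none. Striated muscle genes were accessible at 4 of 20 in each animal, 3 of them shared (adjusted p = 6.2e-05 and 2.2e-04, Fisher's exact test), with Mylpf strongest (12.8 and 8.90) in a window shared with Tbc1d10b, then Tnni3 (1.43 and 0.711) and Tnnc2 (0.932 and 0.80). The highest Mylpf peaks did not overlap, at 127208581 to 127208740 in replicate 1 and 127208801 to 127209180 in replicate 2. The actin genes Acta1 and Actc1 had no promoter peak, although Acta1 had an accessible region in its window in both animals. The muscle call ended with the wide window, at 45.0% against 68.6% of other genes (adjusted p = 0.0346 and 0.0697, Fisher's exact test). Blood and lymphoid genes were accessible at 3 of 20 (adjusted p = 7.9e-06 and 3.7e-05, Fisher's exact test), among them Rag1 (2.51 and 5.09), in a window shared with B230118H07Rik, and Epor (2.40 and 1.22). Alas2 had none. Germline genes were accessible at 3 and 2 of 20 (adjusted p = 7.9e-06 and 4.0e-06, Fisher's exact test). Dazl, an RNA-binding protein gene of germ cells, had heights of 11.8 and 6.95, Sycp3 0.401 and 0.286, and Ddx4 0.244 in replicate 1 alone, while Acrv1 and Akap4 had none. Keratinocyte and epithelial genes were accessible at 5 of 20 (adjusted p = 3.7e-04 and 0.00104, Fisher's exact test), led by the keratin gene Krt10 (12.5 and 9.55), Lgr5 (3.67 and 2.86) and Elf5 (1.95 and 1.17), and Cdx2 and Dsg3 had none. Matched on promoter CpG class, these tissue lists kept their calls, with adjusted p at most 0.0460 (exact stratified test). Expected shares were then lower than the 65.3% of other genes without matching. They were 34.0% for liver, 50.4% for muscle, 38.2% for blood and lymphoid, 50.9% for germline and 49.1% for keratinocyte genes.

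Hox and chemosensory receptor genes mostly lacked a promoter peak. Mapping of reads within these gene families was not examined, so a missing peak need not mean closed DNA. Hox genes, which pattern the body axis, had promoter peaks at 7 of 39 in both animals (Fisher's exact test, adjusted p = 2.2e-09 and 3.9e-08). Hoxa7 was the strongest (5.22 and 3.22), above Hoxc5 (0.965 and 0.810) and Hoxc10 (0.743 and 0.405), and Hoxa11 had no peak. Olfactory receptor genes were accessible at 41 and 25 of 1091 (adjusted p at most 2.3e-299 in both animals, Fisher's exact test). Olfr1121 (2.61 and 2.89), Olfr1324 (1.44 and 2.54) and Olfr523 (1.46 and 0.958) ranked first, and Olfr1 and Olfr10 had none. Vomeronasal receptor genes were accessible at 4 and 1 of 326 (adjusted p = 7.6e-149 and 1.4e-141, Fisher's exact test). The only one in both animals was Vmn1r4 (13.7 and 9.57), whose peak also lay in the window of Nt5c3. Vmn1r200 and Vmn1r203 had heights of 0.195 and 0.146 in replicate 1, and Vmn1r1 and Vmn1r10 had no peak. Hox genes and both receptor families kept their calls when matched on promoter CpG class. Olfactory receptors then stood at 3.02% against 11.1% expected, and against 68.5% of other genes without matching. For vomeronasal receptors it was 0.767% against 8.76% expected and 66.2% without matching. For Hox genes it was 17.9% against 90.6% expected and 65.4% without matching. Across all 21829 protein-coding genes, 14626 and 13869 had a promoter peak, 13733 in both animals and 7067 in neither.

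**Figure D1:**
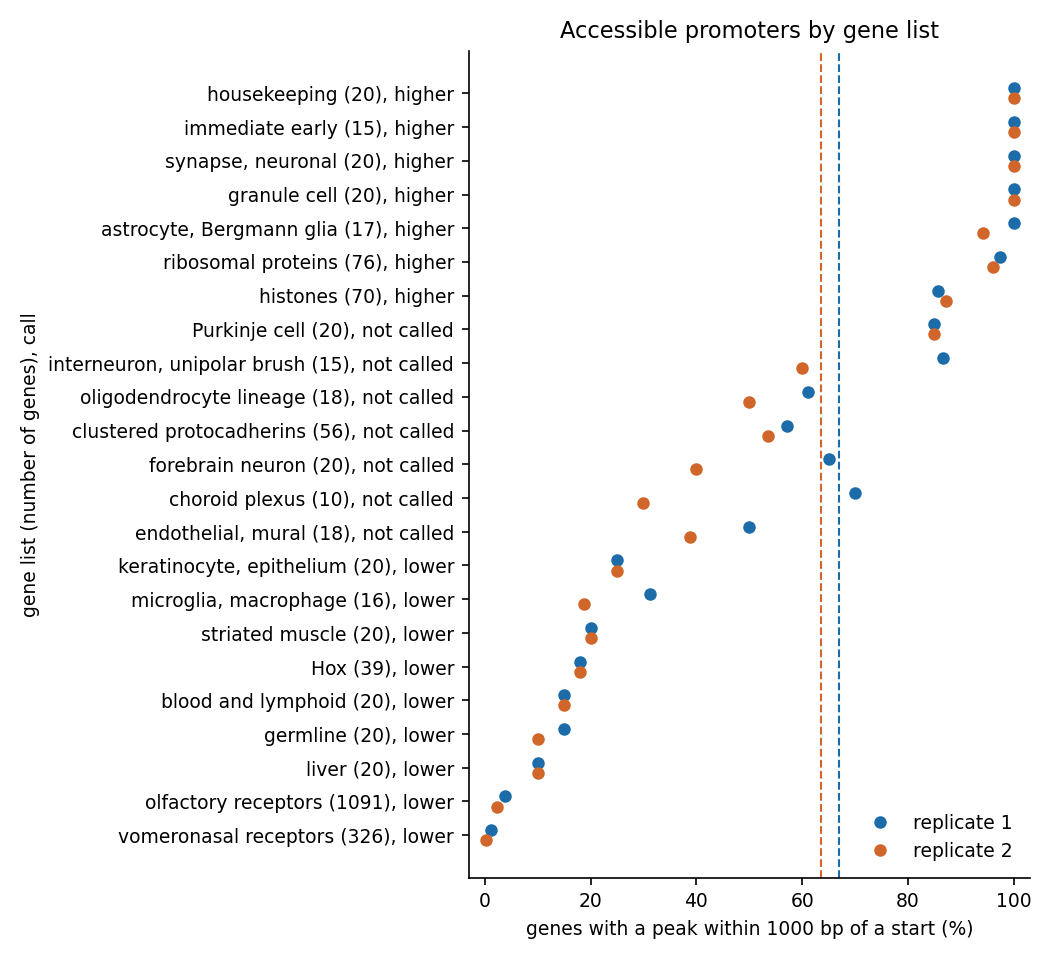
Share of genes in each list with a peak within 1000 bp of an annotated start, in percent, for replicate 1 (blue) and replicate 2 (orange), with the share of all protein-coding genes dashed. Granule cell, synapse, immediate early and housekeeping lists are complete in both animals, and olfactory and vomeronasal receptors below 4%.

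Granule cell, synapse and immediate early genes had more distal peaks than random lists. Granule cell genes had a median of 18 and 14.5 distal peaks, against 3 and 2 for random lists of matched length. Synapse and neuronal genes had 14.5 and 9 against 3.5 and 3, and immediate early genes 7 and 5 against 1 and 1. In all 3 lists the adjusted permutation p was 0.00092 and 0.00115, the smallest that 10000 random lists could give here. Rbfox3, which encodes the neuronal marker NeuN, held 161 and 74 distal peaks and Tiam1 51 and 47. The synaptotagmin gene Syt1 held 48 and 40, Dusp1 12 and 11, and Nr4a3 10 and 7. Vomeronasal receptors had a median of 0 distal peaks against 1 in random lists (adjusted permutation p = 0.00092 and 0.00276), although Vmn2r7 and Vmn2r1 had means of 3 and 2.5. No other list was called, and Purkinje cell genes had medians of 3 and 2 against 3 and 2.5. Protocadherins (6 and 7 against 4 and 3) passed in replicate 2 alone, with adjusted permutation p = 0.108 and 0.00115. So did histone genes (1 and 1 against 0 and 0, adjusted permutation p = 0.316 and 0.0184), which were called higher with 50000 bp on both sides, the same number of peaks and the smaller peak list. Olfactory receptors (0 and 0 against 1 and 1) passed in replicate 1 alone, with adjusted permutation p = 0.00092 and 1.00, and were called lower with 50000 bp and with the mean. With the mean in place of the median and values averaged over the animals, granule cell genes had 23.3 peaks against 6.78. Synapse genes then had 16.4 against 6.67, and neither list was called (adjusted permutation p = 0.0589 in replicate 1 for both). Counting the gene body only ended the calls for immediate early genes and vomeronasal receptors, and protocadherins were then called higher, at 6 peaks against 2 (adjusted permutation p = 0.00115 and 0.00230). The vomeronasal call also ended with the smaller peak list.

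At Neurod1 (chromosome 2, 79452521 to 79456751), the gene and 15000 bp on both sides held 15 and 16 peaks and 52 and 48 footprints. The promoter peak spanned 79456721 to 79457000 in replicate 1 and 79456761 to 79456820 in replicate 2. Neurod1 overlaps the gene model of Cerkl and the long non-coding RNA gene Gm26755, so distal peaks here cannot be assigned to Neurod1 alone.

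**Figure D2:**
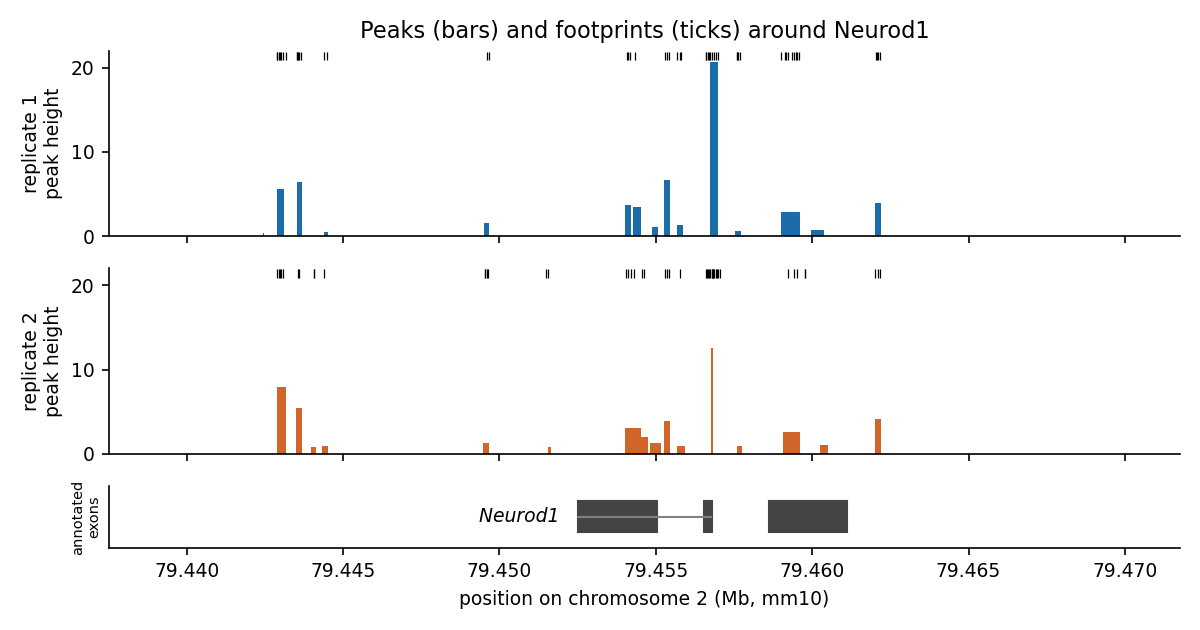
Peaks of replicate 1 (blue) and replicate 2 (orange) as bars of the authors' height, with footprints as black ticks, around Neurod1 on chromosome 2 (Mb, mm10). Dark boxes are annotated exons of any gene, the line is Neurod1, and the tallest bar in both animals, 20.6 and 12.6, stands at its start.

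Of 27 binding motifs tested, 12 were occupied by footprints more often than the same sequence read backwards and 2 less often. Motif and reversed sites were not matched on the height or cuts of their peaks. In replicate 1, a footprint was found in 7.08% of peaks below 25 cuts and in 100% at 1600 or more, counted in steps of height. A difference in peak strength between motif and reversed sites could thus add to these calls. How either sequence is cut without bound protein was not examined, so the calls in both directions do not by themselves show protein binding. Among the called motifs with a ratio in both animals, the largest ratio was that of CTCF, the insulator protein, with 90.5% and 80.9% of sites in a footprint and a mean ratio of 6.81 ± 0.67 (SD, n = 2; Fisher's exact test, adjusted p = 2.0e-15 and 3.6e-05). Its reversed sequence occurred at only 21 and 9 sites. The E-box bound by ATOH and NEUROD factors was occupied at 42.4% and 42.6% of 6643 and 6807 sites, a ratio of 5.05 ± 0.28 (SD, n = 2; Fisher's exact test, adjusted p = 2.0e-93 and 1.8e-80). The cyclic AMP response element followed at 68.7% and 75.0%, with a ratio of 4.58 ± 0.36 (SD, n = 2). Next came the consensus of HNF4 (3.28 ± 0.14) and NFY (3.03 ± 0.023; SD, n = 2 each). ETS (2.50), the short NFI site (2.18) and EGR (2.10) had lower mean ratios. Below these stood the E-box of USF and MYC (1.84), ZIC (1.73) and SOX (1.25). The SOX call is relative to its reversed sequence only. Its sites were occupied at 12.46% and 10.04%, below the 17.2% and 14.6% of all peak bases that lay in footprints. HNF4 sites, at 21.95% and 15.06%, were close to that base share in replicate 2. All other motifs called higher also stood above the base share in both animals. NRF1 sites were occupied at 91.2% and 92.4%, with 6 and 4 backward sites for comparison and no ratio in replicate 2. ERR (0.479 ± 5.3e-04) and FOX (0.512 ± 0.047; SD, n = 2 each) were occupied less often than their reversed sequence. The 13 motifs not called were the full NFI site, MEF2, RFX, AP-1, YY1, REST, ROR, TEAD, the POU octamer, the LIM homeodomain site, PU.1, GATA and HNF1. In replicate 1 alone, the full NFI site (adjusted p = 0.0116) and YY1 (0.0178) passed higher and AP-1 (4.9e-05) lower by Fisher's exact test. TEAD passed higher in replicate 2 alone (adjusted p = 0.0466, Fisher's exact test). The full NFI site, occupied at 72.5% and 50%, had only 4 and 5 reversed sites, and YY1 had 7 in each animal. REST had no reversed site for comparison, RFX 3 and 2 and HNF1 1 and 1, so for these the test could hardly have passed. The SP/KLF site, which had no reversed control, was occupied at 63.8% and 61.1%, while 17.2% and 14.6% of peak bases lay in footprints. In promoter peaks alone the calls ended for ERR (mean shares 5.92% against 15.5% backwards), SOX (10.6% against 10.1%) and HNF4 (11.2% against 7.51%). Outside promoters they ended for NRF1 (74.8% against 50%), ZIC (39.5% against 31.2%), ETS (36.2% against 22.8%), NFY (20.2% against 9.79%) and CTCF, the last still occupied at 85.6% of sites with adjusted p = 0.0915 in replicate 2 by Fisher's exact test.

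**Figure D3:**
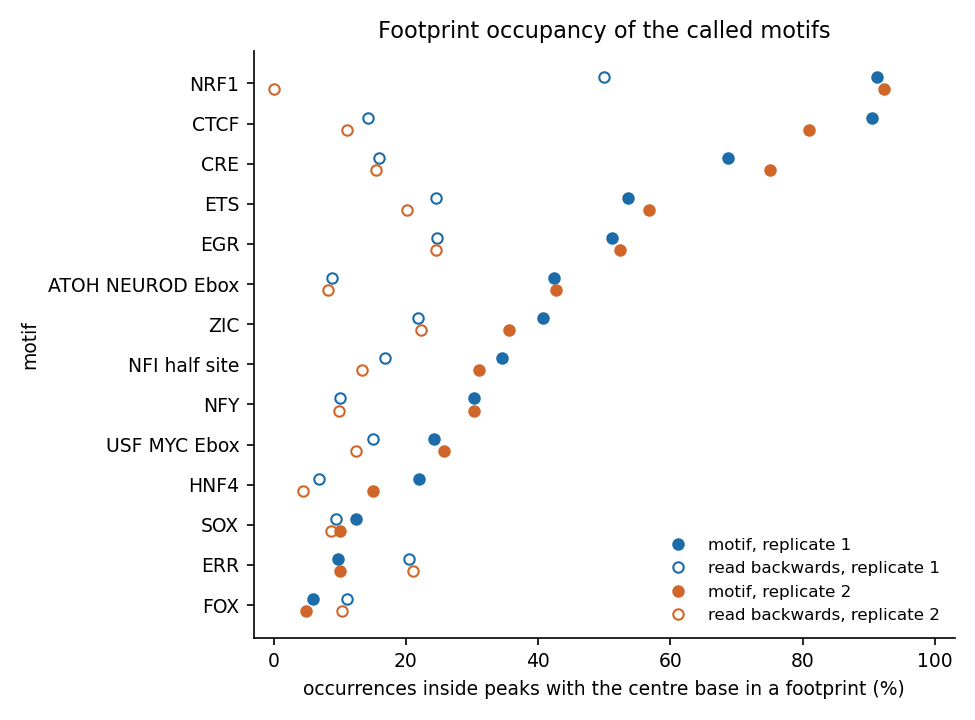
Share of motif occurrences inside peaks whose centre base lay in a footprint (filled) and of the same sequence read backwards (open), in percent, for replicate 1 (blue) and replicate 2 (orange). CTCF and NRF1 sites exceed 80% in both animals, and the FOX and ERR sites lie below their reversed sequence.

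Most strong sites were found in both animals. Of replicate 1 peaks, 65.8% overlapped a replicate 2 peak, and 80.4% of replicate 2 peaks overlapped a replicate 1 peak, against 1.70% and 2.07% for random placements. Promoter peaks were shared at 78.7% and 87.8%, intergenic peaks at 60.5% and 76.4%. Of the strongest 10000 peaks in each animal, 99.9% had a peak in the other, while among the lowest of 10 equal height classes 12% and 33.9% did. Over 90642 pairs of shared peaks the heights had a Spearman correlation of 0.929 across peaks, which are not independent replicates. Footprints were shared at 44.2% and 60.9%, against 12.9% and 17.1% for placements within the same regions. Sharing went from 16.1% and 35.6% at widths of 7 to 8 bp to 95.6% and 98.4% at 31 bp or more. The overlap was counted on the shorter footprint, so a wide footprint could be shared by covering part of a narrow one. Random placements were not split by width, so how far this rise exceeds chance is not known.

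**Figure D4:**
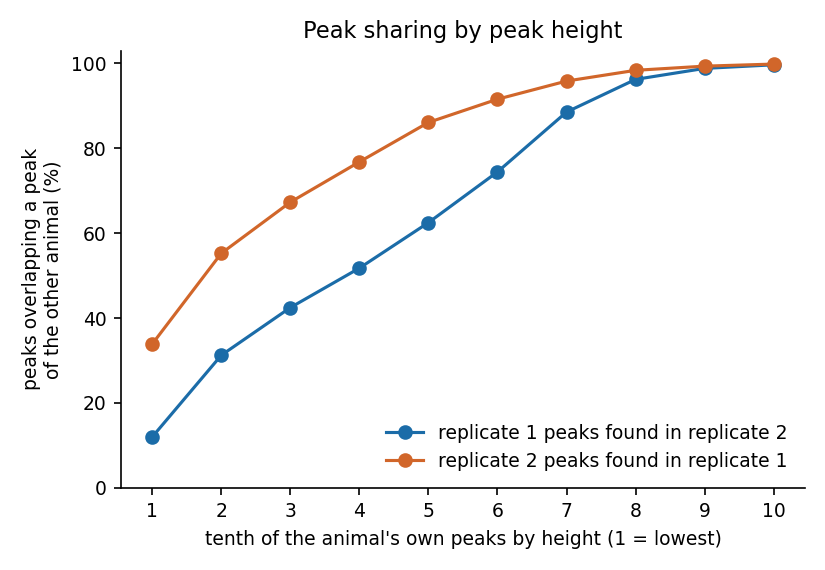
Share of each animal's peaks that overlapped a peak of the other animal, in percent, over 10 equal classes of its own peaks ranked by height from lowest to highest. Sharing went from 12% to 99.7% for replicate 1 peaks (blue) and from 33.9% to 99.9% for replicate 2 peaks (orange).

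Few promoters were accessible in a single animal. A promoter peak in replicate 1 with no region in replicate 2 was seen at 769 genes, and the reverse at 114. The highest-ranked of the first kind were AL732309.1, Gpr153, Carmil2, Gigyf1 and Trip6, with heights from 1.67 to 2.08 (percentile ranks 70.4 to 74.5 in the replicate 1 list). Those of the second kind were Fam196b, Cd300ld3, Tmem52, Osgin1 and Dcdc2b, with heights from 0.632 to 1.06 (percentile ranks 36.9 to 55.4 in the replicate 2 list). With 1 library per animal these differences have no replicate check.

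The X chromosome was sparse in peaks. It carried 24.6 and 19.3 peaks per Mb, which was 0.412 and 0.409 of the autosomal median, a mean ratio of 0.410 ± 0.0018 (SD, n = 2). The density of protein-coding genes on X was 0.723 of the autosomal median. Promoter peaks on X had 0.519 and 0.535 times the median height of autosomal ones. Chromosome 11 was the densest, at 75.7 ± 13 peaks per Mb (SD, n = 2), and chromosome Y held 99 and 38 peaks in all.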

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

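The smaller peak list was chosen as an alternative after seeing the data for annotation, promoter lists and distal lists, and all other settings were chosen before. For the region yield, peaks above the median height numbered 63434 and the smaller list 83605 per animal, against 127266. Mean peak sharing between animals was 87.2% among the strongest 10000 peaks of each list, against 73.1%, and from 64.7% to 76.8% under the other 5 settings. Mean footprint sharing between animals was 56.7% at 1 bp and 42.3% at 90% of the shorter, against 52.6%. The height correlation was 0.944 as Pearson's on log10 heights and 0.875 for the strongest 10000 peaks of replicate 1. In the annotation of peaks, promoters held 13.2% with the narrow window, 29.7% with the wide one, 19.9% of regions, 32.7% of peaks above the median height and 29.0% of the smaller list, against 23.1%. A single animal gave from 22.1% to 24.2%.

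Matching on CpG class left 2 lists higher, against 7, and 10 lower, against 9. The histone list then stood at 86.4%, on the other side of its comparison, and the astrocyte list at 50% among peaks above the median height. The cause was not tested. A single animal gave 7 higher and from 9 to 10 lower. For distal peaks, lists called higher numbered 5 with 50000 bp on both sides and 1 with the mean, against 3. Lists called lower numbered 0 with the gene body only, 2 with 50000 bp, 2 with the mean and 0 with the smaller list, against 1. A single animal gave from 3 to 5 higher, the latter without replicate 1, and from 1 to 2 lower, the latter without replicate 2. Motifs called higher numbered 7 outside promoters, against 12, and motifs called lower numbered 1 in promoter peaks, against 2. Smaller subsets hold fewer sites, and the cause was otherwise not tested. A single animal gave from 13 to 14 higher and from 2 to 3 lower.

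In the chromosome distribution of peaks, the X to autosome ratio was 0.372 for regions and 0.393 for covered bases, and from 0.409 to 0.412 in a single animal. Bases at or below the false discovery rate covered 34.0 Mb at 0.01 and 27.9 Mb at 0.001, against 41.5 Mb at 0.05. Single lists kept their side of the threshold in 189 of 207 promoter values, 146 of 161 distal values and 121 of 133 motif values. Heights of named genes moved by more than the spread between animals in 5 of 59 values with the narrow window and 3 of 68 with the wide one. Sharing without a replicate, another value column and a stricter set of footprints could give no value. No paired analysis was possible because there was 1 group. A single animal gave 114404 or 140127 peaks. Sharing was lowest among the lowest peaks, and how far depth contributed is open.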

Other observations

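The tests of whole-library depth and of X copy number were chosen after the result was seen, as were the non-coding summary and the ranking of distal peaks.

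Peaks also lay near annotated starts of genes outside the protein-coding set. Of 2959 antisense RNA genes, 42.0% ± 2.6 (SD, n = 2) had a peak within 1000 bp of a start, of 5854 long intergenic RNA genes 23.5% ± 2.2, and of 9940 processed pseudogenes 7.03% ± 2.3 (SD, n = 2 each). Peaks that also lay in promoter windows of protein-coding genes were not removed, and no random level was computed. These shares therefore do not show that the non-coding starts themselves were accessible. Ranked by distal peaks over the mean of their length class, the first 10 genes were Gm20388, Uncx, Zic2, Fgfr2, Trim62, Gm37419, Bcl9l, Slc22a12, Shisa8 and Neurod2. Zic2 held 20 and 24 distal peaks against class means of 1.62 and 1.10, Uncx 20 and 26, Trim62 45 and 23, Bcl9l 51 and 15, and Neurod2 17 and 16. Gm20388 and Fgfr2 are very long gene models that span other genes. In some of the genes ranked high the animals differed, as at Cntn2 with 53 and 7.

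Many peaks were found in a single animal, 47955 in replicate 1 and 22371 in replicate 2. Greater depth of replicate 1, as 1 factor for all DNA, would leave unshared peaks of the same height alike in GC content. Depth acting only in that way cannot be the whole cause, since unshared peaks of replicate 1 were higher in GC in all 10 height classes, by at least 3.43 percentage points in the median. The peaks were matched on height and not on cuts, and the bound was set after the result was seen. Other effects of depth therefore remain open. A candidate explanation is that GC-rich DNA was recovered differently in the libraries, as unshared peaks of replicate 1 exceeded those of replicate 2 in median GC content by 6.32 percentage points at matched height, and by at most 8.13 in a class. Over shared pairs, the median log2 ratio of replicate 1 to replicate 2 height rose from -0.138 in the lowest of 10 GC classes to 0.645 in the highest. These pairs were not matched on height. The ratio also rose with height, from 0.00893 in the lowest 10% of pairs to 0.619 in the highest 10%. No biological explanation was tested.

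Promoter peaks on X were lower than on autosomes. Promoter CpG content as the cause would need a ratio of at least 0.8 within CpG classes, and the mean ratio was 0.523, with bootstrap intervals over X genes from 0.416 to 0.597 in replicate 1 and from 0.485 to 0.623 in replicate 2. Each autosome against the others gave from 0.811 to 1.34. The ratios were 0.487 and 0.559. The single X of males and X-linked regulation cannot be told apart, since females were not analysed here. The range expected of a single X was also set after similar ratios were seen. Loss of CAST sequence in mapping could lower the X ratio only if the X came from the CAST parent. The direction of the cross is not stated beyond the strain name. If that name gives the mother first, the X was not CAST. Such loss would then lower autosomal peaks and raise the ratio. Mapping was not tested.

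Replicate 1 had a footprint in more of its peaks, by 5.93 percentage points. At the same number of cuts per peak, counted in steps of height, the difference was -4.15 points, so more cuts per peak could account for the excess. The classes ranged from -8.23 to 0, and 2 of the 8 lay beyond the bound of 5 points set before the test. The cut numbers rest on the grid of heights. No biological explanation was tested.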
